A study of Arabidopsis thaliana with 6 samples.

How the data were processed

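Transcript levels were measured by RNA sequencing in 6 Arabidopsis thaliana libraries, 3 of the wild type Col-0 and 3 of the cdc5 mutant, all labelled as rosette leaves. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads, the complementary strand was marked with dUTP and removed, and read pairs were sequenced on an Illumina instrument. Samples were grouped by their genotype label, and replicate numbers came from their titles. Titles of both genotypes end in the same numbers, which were read as replicate numbers, but those of the mutant can also be read as names of alleles. In that case the cdc5 means and SDs would span alleles in place of replicates of a single one. Nothing in the labels says that the 3 libraries of a genotype came from separate plants, so p-values measure only the spread between these samples, which may be technical.

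The authors deposited a single table with an FPKM value (fragments scaled by transcript length and library total) for each of 45666 transcripts of 27947 genes in each library. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, DESeq2 and edgeR, without their roles or order. The genome build in those notes is one of the mouse and cannot apply to this table. Of 27684 nuclear genes, 97.8% had the same span in the TAIR10.1 annotation, and coordinates are printed as the table gives them. Whether fragments were assigned by strand, and how fragments that fit several transcripts or gene copies were shared out, is not given in the sources used here. The deposited fold column is the ratio of the mean FPKM in cdc5 to that in Col-0, checked wherever both were above 0, and the deposited log2 column is its logarithm. The deposited p-value and q-value columns come from a test by the authors that the table does not name, and the q-value equals a Benjamini-Hochberg adjustment over all transcripts to within 6.5e-05. The authors marked as significant the 5566 transcripts with a q-value under 0.05 and a fold change of at least 2.

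Depth was estimated from the steps between low FPKM values, because the table holds no read counts. Of transcripts that were the sole one of their gene and at least 600 bases long, those with low values lay within 0.1 of a whole multiple of a step in 59.9% to 65.0% of cases per library. A step not fitted to the values would give 20%. Each step was the best fit to these same values within a fixed range of steps. The 20% is therefore not a strict chance level, and the depth could only fall within a limited range. The steps correspond to 23.6, 19.0 and 22.9 M fragments in Col-0 replicates 1, 2 and 3, and to 25.1, 25.5 and 20.1 M in cdc5 replicates 1, 2 and 3. A level of 3 fragments over 1 kilobase lies between 0.118 and 0.158 FPKM. These floors cover counting error only. Squared differences between libraries of the same genotype were 2.06 to 2.69 times what counting alone would give, so no library was treated as a copy of another. The steps were not whole for enough transcripts to recover counts, and no count model was fitted.

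A gene's level was the sum of its transcripts' FPKM. Genes and transcripts with a mean of at least 1 FPKM over the 6 libraries were compared with limma 3.58.1 (R 4.3.3, with data.table, version 1.17.8) on log2(FPKM + 1), with an intensity trend and robust empirical Bayes moderation, no covariate, and a Benjamini-Hochberg adjusted p under 0.05. A fold change on this scale understates changes of low genes. Every adjusted p below comes from limma unless another source is named, and values after ± are standard deviations (SD) over n = 3 libraries. With 3 libraries against 3, an exact permutation test of a single value cannot give a p below 0.10. Isoform usage was tested with limma's diffSplice (Simes p per gene) in genes with at least 2 tested transcripts, and its size is the change in a transcript's share of the gene's summed FPKM, in percentage points. Gene lists were compared with all other genes by camera with a preset correlation of 0.01, again with an estimated correlation, and by fry, which asks whether a list's genes move one way on balance without comparing them with others. P-values of lists were adjusted over the 19 lists with at least 3 tested genes. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

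The groups, tests, gene lists and most alternatives were fixed before the data were examined. Genes named in the text are CDC5, the FLC clade and SEF, the 10 genes with the highest and the 10 with the lowest log2 fold change, up to 4 members of each list with the smallest adjusted p, and the 6 genes with the smallest adjusted p for isoform usage. The 20 genes of extreme change had to pass the test, to have no overlap between the genotypes' libraries and to reach 5 FPKM in the higher group. The 6 isoform genes had to include a share change of at least 20 points. Where another gene is named, it was chosen after its values were seen. Alternatives were a pseudocount of 0.1, no filter, a filter at 5 FPKM, cyclic loess scaling between libraries, a replicate block, plain empirical Bayes moderation, an F test for isoform usage, the authors' q-values, and each library left out in turn. An adjustment for transcript length and GC content within each library, and a run on genes that overlap no other gene, were added after the data were seen. GC content was always that of the gene's genomic span, introns included. A second heat list of 11 genes and a second flower list of 12 were drawn up before their values were examined, and a list of 16 mitochondrial stress genes was drawn up afterwards. Gene Ontology terms listed in the deposited table with 15 to 300 tested genes were also tested with camera, as a search not planned in advance. The slope on exon number was fitted with natural splines of 5 degrees of freedom for length, level and GC content, also after the data were seen.

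The procedure was tested on simulated libraries with the means, depths and replicate spread of the real ones, in which transcripts of a gene varied independently. Of 67 genes changed 1.5-fold 83.6% were recovered, of 67 changed 2-fold 94% and of 66 changed 4-fold 95.5%, with 16 unchanged genes called among 19772 tested. The real libraries gave 11027 calls among 19778 genes, a far larger share, so the share of false calls there was not measured. Of 67 transcripts changed 1.5-fold 41.8% were recovered, of 67 changed 2-fold 71.6% and of 66 changed 4-fold 90.9%, with 13 unchanged ones called among 27313 tested. Isoform usage was recovered in 176 of 200 changed genes among 5434 tested, with 12 unchanged genes called. In that simulation every gene kept its summed level, so usage calls in genes whose level also changed were not tested. Of 21 simulated lists, the 1 raised by 1.3-fold was called and none of the 20 unchanged ones. Simulated genes also varied independently of each other, so false calls of lists among correlated genes were not tested. In the real libraries, splits that mixed the genotypes called up to 6 lists, against 8 for the real split. Genes that overlap others (8015 in the table, 6793 of them with a partner on the other strand) and near-identical gene copies are reported as uncertain.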

Results

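The deposited table described RNA from 3 Col-0 and 3 cdc5 libraries labelled as rosette leaves. CDC5 is a MYB-related protein of the MOS4-associated complex, a partner of the spliceosome. The series title places CDC5 in the control of flowering time through FLC, SEF and the MAF genes, so these genes and their transcripts come first. Estimated depth was 19.0 to 23.6 M fragments in Col-0 and 20.1 to 25.5 M in cdc5.

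The CDC5 transcript (AT1G09770, chromosome 1, 3161832 to 3165616) was lower in every cdc5 library but was still detected. Its level was 37.1 ± 1.08 FPKM in Col-0 and 21.3 ± 0.418 in cdc5 (SD, n = 3 each), or 57.5% of the Col-0 mean. The log2 fold change was -0.77 (SE 0.043, limma adjusted p = 2.3e-06). The table lists 1 transcript for CDC5, and its annotated 3' end overlaps AT1G09780 on the opposite strand, which stood at 72.0 FPKM in Col-0 and 67.8 in cdc5. Reads from that overlap cannot be assigned with certainty. An FPKM value over the whole transcript cannot show whether the RNA left in cdc5 is intact, which was not examined here.

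FLC, the MADS-box repressor of flowering, and its relatives FLM, MAF2 and MAF4 fell in cdc5, while SEF rose. FLC (AT5G10140, chromosome 5, 3173382 to 3179448) fell from 2.88 ± 0.503 to 1.28 ± 0.346 FPKM, a log2 fold change of -0.77 (SE 0.143, limma adjusted p = 0.0018). MAF4 (AT5G65070, chromosome 5, 25992193 to 25996202) fell furthest of this group, from 2.75 ± 0.435 to 0.649 ± 0.384 FPKM, with a log2 fold change of -1.21 (SE 0.18, limma adjusted p = 5.4e-04), or -2.07 with a pseudocount of 0.1. FLM (AT1G77080, chromosome 1, 28955483 to 28960234) reached 77.6% of its Col-0 mean of 32.3 ± 1.08 FPKM, and MAF2 (AT5G65050, chromosome 5, 25982254 to 25986435) 77.9% of 40.4 ± 2.45 FPKM, with limma adjusted p = 0.0055 and 0.0014. SEF (AT5G37055, chromosome 5, 14641442 to 14642513), a subunit of the SWR1 chromatin remodelling complex listed as SWC6, rose from 7.09 ± 1.36 to 10.7 ± 1.098 FPKM, a log2 fold change of 0.54 (SE 0.131, limma adjusted p = 0.009).

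MAF3 (AT5G65060, chromosome 5, 25987309 to 25991412) and MAF5 (AT5G65080, chromosome 5, 25997504 to 26002619) did not pass the test, with log2 fold changes of 0.16 and -0.10 and limma adjusted p = 0.4 and 0.43. MAF5 passed without cdc5 replicate 2, at -0.22 (limma adjusted p = 0.033, range over all alternatives 0.033 to 0.86). MAF3 gave 0.29 without Col-0 replicate 2 and 0.01 without Col-0 replicate 3, and MAF5 gave -0.03 without cdc5 replicate 1 and -0.05 without cdc5 replicate 3. After loess scaling and after length and GC adjustment the values were 0.04 and 0.26 for MAF3 and -0.22 and -0.06 for MAF5. The 7 genes of the group gave 1 higher and 4 lower, and 5 also when adjusted over the list alone. As a set they did not stand apart from other genes (camera adjusted p = 0.15). Fry, which makes no such comparison and called 17 of the 19 lists, placed them lower (fry adjusted p = 0.003). The set includes SEF, which rose, and the clade without SEF was not tested as a set. FLC lies within the span of an antisense long noncoding RNA, AT5G01675, listed at 0.371 FPKM in Col-0 and 0.248 in cdc5.

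**Figure D1:**
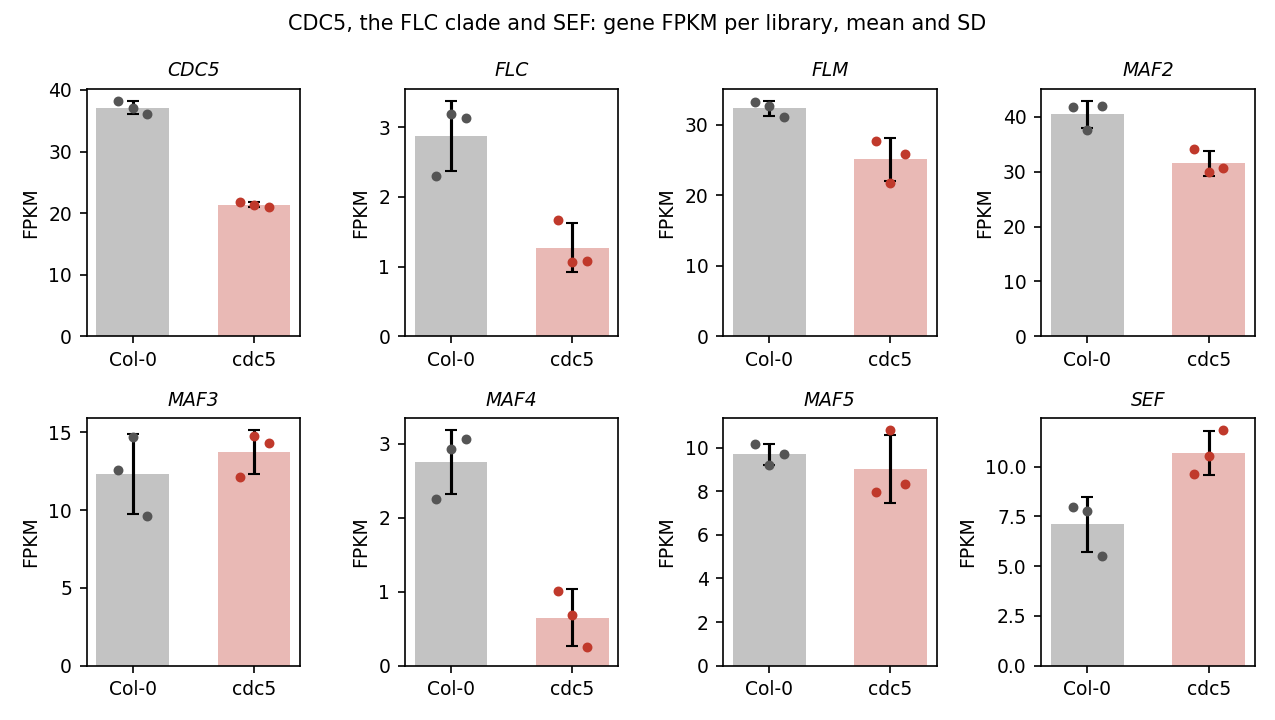
Gene level in FPKM (vertical axes, from 0) of CDC5, the FLC clade and SEF in each Col-0 and cdc5 library; bars are means, error bars SDs over 3 libraries and points single libraries. CDC5, FLC, FLM, MAF2 and MAF4 show no overlap between the genotypes and are lower in cdc5, SEF is higher, and MAF3 and MAF5 overlap.

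Single transcripts of the clade moved unequally, and with a pseudocount of 0.1 the log2 fold changes of AT5G65070.1 and AT5G65060.3 became -3.94 and 1.95. MAF4 transcript AT5G65070.1 fell from 2.03 ± 0.448 to 0.052 ± 0.09 FPKM, a log2 fold change of -1.52 (SE 0.205, limma adjusted p = 0.0047). MAF2 transcript AT5G65050.5 fell from 13.97 ± 2.11 to 6.59 ± 0.682 FPKM, a log2 fold change of -0.97 (SE 0.131, limma adjusted p = 0.0046). MAF3 transcript AT5G65060.3, which holds the whole intron at chromosome 5, 25990656 to 25990963, rose from 0.609 ± 0.317 to 2.43 ± 0.412 FPKM, a log2 fold change of 1.11 (SE 0.214, limma adjusted p = 0.014, or 0.053 without cdc5 replicate 3, range over alternatives 0.019 to 0.053). FLC transcript AT5G10140.1 gave -0.75 (limma adjusted p = 0.028) and the SEF transcript 0.54 (limma adjusted p = 0.046). The FLC transcript missed the threshold without Col-0 replicate 2 or 3 or cdc5 replicate 2 or 3 (limma adjusted p from 0.079 to 0.085). It also missed it with a replicate block (0.1), with a range over alternatives of 0.017 to 0.1. The SEF transcript missed the threshold without any 1 of the 6 libraries (limma adjusted p from 0.058 to 0.13). It also missed it after cyclic loess scaling (0.072), with no filter (0.068) and with a replicate block (0.13), with a range over alternatives of 0.036 to 0.13.

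Within the clade, the share of transcripts passed the test in MAF3, and whether MAF3 differed from FLM, MAF2 and MAF5, the other members with at least 2 tested transcripts, was not tested. The intron-holding AT5G65060.3 made up 5.33 ± 3.15% of MAF3 in Col-0 and 17.84 ± 3.24% in cdc5 (limma diffSplice adjusted p = 0.035). That call missed the threshold after cyclic loess scaling (adjusted p = 0.054), with a replicate block, and without Col-0 replicate 2 or cdc5 replicate 1, 2 or 3. Without these libraries the diffSplice adjusted p was 0.12, 0.11, 0.061 and 0.14 in turn, with a range over alternatives of 0.029 to 0.14. Among these members, the largest share change was 12.5 points in MAF3, 11.5 in FLM, 13.4 in MAF2 and 17.7 in MAF5. Without single libraries it ranged from 10.7 to 14.4, 5.3 to 20.4, 12.2 to 15.2 and 3.9 to 26.1 in the same order. FLC, MAF4 and SEF had fewer than 2 tested transcripts, so their usage was not tested. For SEF only AT5G37055.1 is listed, so SEF RNA spliced in other ways could not be told apart from it. In MAF4, which stood at 0.649 FPKM in cdc5, AT5G65070.1 went from 73.82 ± 11.69% in Col-0 to 7.59 ± 13.15% in cdc5. For FLM, MAF2 and MAF5 the limma diffSplice adjusted p was 0.84, 0.41 and 0.2, and MAF2 passed without cdc5 replicate 2 (adjusted p = 0.035, range over alternatives 0.035 to 0.57). In the authors' deposited table, AT5G65060.3, AT5G65070.1, AT5G65050.5 and AT5G10140.1 were marked as significant with q-values of 7.28e-04, 3.10e-03, 2.39e-11 and 3.62e-04. It also marked FLM transcripts AT1G77080.3, AT1G77080.6 and AT1G77080.7 as higher in cdc5, which stayed under the filter here with 0.941, 0.226 and 0.097 FPKM in cdc5.

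Across all genes, many small changes separated the genotypes. Of 19778 genes tested, limma called 6594 higher and 4433 lower in cdc5, and 236 of the higher and 324 of the lower genes changed at least 2-fold on the log2(FPKM + 1) scale. These 2-fold counts were 435 and 568 with a pseudocount of 0.1, 84 and 214 with a filter at 5 FPKM, and 99 and 245 without overlapping genes. With the pseudocount of 1 and the filter at 1 FPKM, protein-coding genes gave 123 of the 2-fold increases and 307 of the 2-fold decreases. Long noncoding RNAs gave 71 and 6, and small nucleolar RNAs 29 and 2. The libraries were selected for polyadenylated RNA, and whether small nucleolar RNA values reflect mature molecules or longer RNA was not tested. In 12585 genes (63.6%) the libraries of the genotypes did not overlap, against 10% by chance.

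The balance between higher and lower genes depended on scaling. It was 59.8% higher as deposited, 50.3% after cyclic loess scaling (5197 higher, 5145 lower) and 50.4% after adjustment for length and GC content (5178 higher, 5104 lower). Longer genes lay higher in cdc5, with a median log2 fold change of -0.09 in the shortest 1973 nuclear genes and 0.20 in the longest 1973. Long noncoding RNAs that overlap another gene gave 166 higher and 41 lower, where reads cannot be assigned with certainty. Those that overlap none gave 13 higher and 15 lower, or 10 and 16 after loess scaling and 14 and 14 after length and GC adjustment. Small nucleolar RNAs that overlap another gene gave 28 higher and 3 lower (median log2 fold change 0.97), and those that overlap none 21 and 13 (median 0.15), or 16 and 13 after loess scaling and 21 and 5 after length and GC adjustment.

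**Figure D2:**
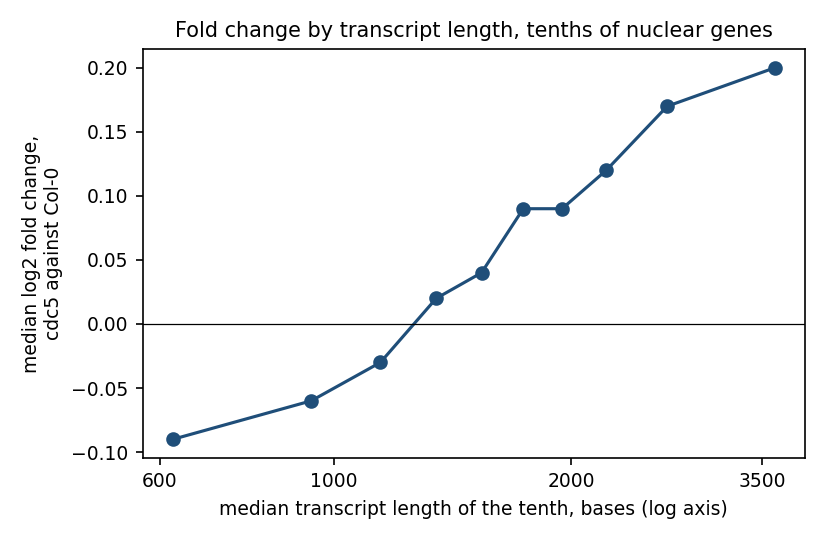
Median log2 fold change of cdc5 against Col-0 (vertical axis) of nuclear genes in 10 groups of equal size by transcript length in bases (horizontal axis, log scale); each point is a group. The median climbs from -0.09 at a median length of 624 bases to 0.20 at 3629 bases.

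The genes with the strongest increases included QQS, ERF071, anac044 and FSD1. QQS (AT3G30720), a gene that affects starch content, rose 18.7-fold from 3.37 ± 0.272 to 62.9 ± 5.36 FPKM (log2 fold change 3.87, SE 0.074, limma adjusted p = 4.5e-09). ERF071 (AT2G47520), an ethylene response factor also known from oxygen shortage, went from 0.210 ± 0.076 to 12.6 ± 0.477 FPKM, and anac044 (AT3G01600), a NAC factor of the DNA damage response, from 0.237 ± 0.031 to 9.87 ± 0.978 FPKM (limma adjusted p = 1.9e-08 and 7.1e-08). FSD1 (AT4G25100), the iron superoxide dismutase of the chloroplast, rose 9.85-fold to 56.5 ± 14.5 FPKM (limma adjusted p = 9.1e-05). AT2G41730 rose from 0.25 ± 0.105 to 7.24 ± 0.332 FPKM. AT4G29200, described as related to beta-galactosidase, was listed at 0 in all 3 Col-0 libraries and at 18.0, 17.2 and 18.7 FPKM in cdc5.

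The other 4 of the 10 highest genes overlap a neighbour. AT3G02205 and AT5G01495 are small nucleolar RNAs inside the spans of protein-coding genes on the same strand. AT3G02205 rose from 2.65 ± 1.56 to 71.2 ± 6.95 FPKM while its host AT3G09440 went from 397 to 54.3 FPKM. AT5G01495 was listed at 0 in all Col-0 libraries and at 6.16, 5.99 and 4.81 FPKM in cdc5. The long noncoding RNA AT3G03475 rose from 0.361 ± 0.325 to 10.4 ± 2.31 FPKM. ATPP2-A10 (AT1G10155) rose from 0.0900 ± 0.107 to 7.32 ± 1.07 FPKM, while PP2A10 (AT1G10150), which overlaps it on the opposite strand, stood at 12.5, 11.1 and 13.2 FPKM in Col-0 and was listed at 0 in all 3 cdc5 libraries. AT5G08180, the host of AT5G01495, went from 59.9 to 84.6 FPKM. Neither AT5G08180 nor AT3G09440 passed the test (limma adjusted p = 0.28 and 0.09). AT3G17390, which overlaps AT3G03475 on the opposite strand, rose from 288 to 329 FPKM (limma adjusted p = 6.7e-04). Reads of overlapping genes cannot be assigned with certainty.

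Heat shock genes fell most. All 9 genes of the heat shock list were lower in cdc5 (9 also when adjusted over the list alone), with a median log2 fold change of -2.12 (camera adjusted p = 1.9e-09, and adjusted p = 0.11 with an estimated correlation). HSP18.2, a small chaperone, fell from 126 ± 3.17 to 14.5 ± 0.406 FPKM, HSP22.0 from 240 ± 3.51 to 36.7 ± 1.07, HSP17.6II from 297 ± 8.40 to 67.6 ± 3.15 and HSP90.1 from 449.8 ± 17.41 to 142 ± 2.47, each with a limma adjusted p of 7.3e-09 or less. Of the 10 genes with the lowest fold changes, 8 encode chaperones. They are HSP21, HSP18.2, HSP17.6C, HSP70-5, HSP26.5, HSP22.0, HSP23.6 and the DnaJ-domain gene AT1G71000, with log2 fold changes from -3.44 to -2.65. The others were PP2A10 and the long noncoding RNA AT5G59732, which stood at 46.6, 37.9 and 28.7 FPKM in Col-0 and was listed at 0 in cdc5. It overlaps AT5G59730 on the opposite strand, which went from 13.0 to 45.6 FPKM. Small heat shock genes of 1 class are similar enough to share reads.

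Genes of other stress responses were also lower. In the abscisic acid and cold list, 11 of 16 tested genes fell and none rose (11 when adjusted over the list alone), with a median log2 fold change of -0.57 (camera adjusted p = 6.3e-05, and adjusted p = 0.11 with an estimated correlation). The dehydrin gene ERD10 fell from 192 ± 4.67 to 111 ± 4.29 FPKM, COR47 from 107 ± 2.35 to 83.0 ± 2.51, COR15B from 20.1 ± 0.963 to 13.0 ± 0.709 and the cold regulator CBF3 from 3.64 ± 0.329 to 1.06 ± 0.214, with limma adjusted p between 1.0e-06 and 6.2e-05. KIN1 and KIN2, and the CBF genes, are near copies of each other, so their separate levels are uncertain.

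In the jasmonate list, 8 of 12 tested genes fell and 2 rose (10 when adjusted over the list alone), with a median of -0.61 (camera adjusted p = 0.008, and adjusted p = 0.29 with an estimated correlation). The storage protein gene VSP2 fell from 579 ± 16.4 to 364 ± 4.11 FPKM, the jasmonate synthesis gene OPR3 from 86.3 ± 3.04 to 48.5 ± 1.53 and LOX3 from 75.2 ± 2.04 to 47.4 ± 1.29. The thionin gene THI2.1 rose from 238 ± 9.06 to 360 ± 11.1 FPKM. MYC2, the central regulator of this response, was listed near 0 in all libraries (means of 0.004 and 0 FPKM), which can be a failed estimate. In the salicylic acid list, 3 genes rose and 6 fell of 17 tested (9 when adjusted over the list alone), among the latter SARD1, WRKY70, WRKY40 and NIMIN1 with log2 fold changes of -0.56, -0.32, -0.32 and -0.92. That list gave 1 higher and 8 lower after loess scaling and 1 and 9 after length and GC adjustment. It passed with a filter at 5 FPKM (camera adjusted p = 0.021) and after length and GC adjustment (0.045) but not as deposited (0.17), with a range over alternatives of 0.021 to 0.29. Its median of -0.11 became -0.20 after loess scaling, -0.18 after that adjustment, -0.07 with no filter, -0.06 without Col-0 replicate 2 and -0.07 without cdc5 replicate 2.

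Genes upstream of FLC were mostly higher. Of 15 FLC activators, 10 rose and 1 fell (11 when adjusted over the list alone), with a median log2 fold change of 0.25 (camera adjusted p = 0.034, and adjusted p = 0.29 with an estimated correlation). VIP5 of the PAF1 complex rose from 13.1 ± 0.260 to 18.0 ± 0.352 FPKM, the histone methyltransferase gene SDG8 from 11.1 ± 0.098 to 15.6 ± 0.631 and PIE1, the motor subunit of the SWR1 complex, from 8.97 ± 0.358 to 13.5 ± 0.730. ARP6, another SWR1 subunit, fell from 16.7 ± 0.581 to 12.9 ± 0.623 FPKM. The list's call ended after length and GC adjustment, with 4 higher and 1 lower and a median of 0.13 (camera adjusted p = 0.12). It also ended with a filter at 5 FPKM (0.053), without cdc5 replicate 2 (0.053) and with a replicate block, with a range over alternatives of 0.0098 to 0.29. SDG8 and PIE1 kept their calls with smaller log2 fold changes after that adjustment, 0.21 and 0.29 against 0.46 and 0.54.

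The autonomous pathway, whose members repress FLC, gave 5 higher and 1 lower of 9 genes (7 when adjusted over the list alone), but 2 higher and 2 lower after loess scaling and 2 higher and 3 lower after length and GC adjustment (camera adjusted p = 0.56 as deposited). REF6, a histone demethylase gene, rose from 11.02 to 17.61 FPKM and FLK from 36.8 to 45.1 FPKM (limma adjusted p = 3.9e-05 and 0.0013). LD and FY, at log2 fold changes of 0.28 and 0.23, lost their calls after loess scaling (limma adjusted p = 0.051 and 0.12) and after length and GC adjustment (0.29 and 0.38), with ranges over alternatives of 0.0038 to 0.29 and 0.0058 to 0.38.

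Among floral integrators and timing regulators, 3 rose and 7 fell of 19 tested (10 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.17, or 0.029 with a filter at 5 FPKM, range over alternatives 0.029 to 0.31). FT, the mobile signal for flowering, fell from 11.3 ± 0.497 to 6.75 ± 0.545 FPKM, SPL3 from 179 ± 9.04 to 132 ± 1.94 and SPL9 from 62.6 ± 1.45 to 49.6 ± 0.776, while TOE2, a repressor of flowering, rose from 7.74 ± 0.375 to 11.7 ± 0.411, with limma adjusted p between 4.0e-05 and 1.2e-04. Of 20 clock and photoperiod genes, 5 rose and 5 fell (10 when adjusted over the list alone; camera adjusted p = 0.96), or 6 and 5 after loess scaling and 4 and 6 after length and GC adjustment. The morning genes LHY and CCA1 rose from 43.5 to 87.3 and from 43.9 to 66.5 FPKM, COL2 rose from 15.8 to 19.9 FPKM and the evening gene LUX fell from 6.77 to 4.16 FPKM. The mix of tissue or the harvest conditions may have differed between the genotypes. Neither was tested for these genes, the FLC clade or the photosynthesis genes.

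Partners of CDC5 rose together. Of 9 genes of the MOS4-associated complex, 8 were higher in cdc5 and none lower (9 when adjusted over the list alone), with a median log2 fold change of 0.42 (camera adjusted p = 0.0048, and adjusted p = 0.27 with an estimated correlation). MAC7 rose from 11.5 to 19.5 FPKM, MAC5A from 27.6 to 39.7, MOS4 from 36.5 to 49.3 and MAC3A from 32.9 to 43.3, with limma adjusted p between 1.4e-05 and 1.4e-04. Splicing factors went both ways, with 12 higher and 9 lower of 25 (22 when adjusted over the list alone; camera adjusted p = 0.98). Their median was 0.12 and their mean 0.01, while camera placed them on the lower side, and they gave 13 higher and 6 lower after loess scaling and 8 and 9 with a median of 0.05 after length and GC adjustment. The glycine-rich RNA-binding genes GRP8 and GRP7 fell from 122 ± 2.43 to 63.2 ± 1.97 and from 137 ± 4.62 to 98.1 ± 2.13 FPKM, and RSZ22a and SC35 rose from 56.8 to 81.3 and from 39.2 to 52.7 FPKM.

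Targets of microRNAs were more often higher. Of 44 such genes, 26 rose and 5 fell (32 when adjusted over the list alone), with a median log2 fold change of 0.23 (camera adjusted p = 0.014, and adjusted p = 0.29 with an estimated correlation). After length and GC adjustment 20 were higher and 8 lower with a median of 0.12, and after loess scaling 23 and 6. The leaf polarity gene PHV rose from 21.96 to 40.6 FPKM and the growth regulator GRF3 to 17.7 FPKM, 1.753 times its Col-0 level. The copper/zinc superoxide dismutase genes CSD1 and CSD2 fell from 578 ± 8.31 to 314 ± 13.9 and from 316 to 175 FPKM, opposite to FSD1. Of 10 genes for making microRNAs, 6 rose and 1 fell (7 when adjusted over the list alone; camera adjusted p = 0.27), or 4 and 2 after loess scaling and 3 and 2 after length and GC adjustment. CBP80 rose from 19.8 to 28.0 FPKM, SE from 27.4 to 34.5 and HYL1 from 10.03 to 12.9. HST, at a log2 fold change of 0.37, lost its call after length and GC adjustment (limma adjusted p = 0.099, range over alternatives 6.9e-04 to 0.099).

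Genes of dividing cells were higher. In the cell cycle list, 12 of 18 genes rose and 2 fell (14 when adjusted over the list alone), with a median log2 fold change of 0.32 (camera adjusted p = 0.014, and adjusted p = 0.33 with an estimated correlation). The ribonucleotide reductase gene TSO2 rose from 55.8 to 84.4 FPKM, CYCD3;1 from 19.1 to 29.1, MCM2 from 19.6 to 28.6 and PCNA1 from 32.8 to 44.3. Of 6 tested shoot meristem markers, 5 rose and 1 fell (6 when adjusted over the list alone), with a median of 0.65 (camera adjusted p = 0.041, and adjusted p = 0.29 with an estimated correlation). KNAT1 rose from 27.0 ± 1.67 to 44.2 ± 0.441 FPKM, KNAT2 from 3.95 ± 0.431 to 10.02 ± 0.949, KNAT6 from 13.0 ± 0.103 to 20.3 ± 0.857 and CUC3 from 1.64 ± 0.231 to 3.72 ± 0.247, and WUS fell from 19.0 ± 1.83 to 15.2 ± 0.613. The meristem call ended without Col-0 replicate 2 (camera adjusted p = 0.057), without cdc5 replicate 2 (0.053) and with a filter at 5 FPKM (0.097). It also ended with a replicate block, with a range over alternatives of 0.023 to 0.29. The flower organ gene AP3 stood beside these meristem markers at 140.1 FPKM in Col-0 and 104 in cdc5.

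Flower organ genes were abundant in libraries of both genotypes, although these were labelled as rosette leaves. PI stood at 190.6 ± 32.4 FPKM in Col-0 and 118 ± 15.8 in cdc5, SEP3 at 152 ± 5.75 and 135 ± 15.4, AP3 at 140.1 ± 3.08 and 104 ± 0.741, AP1 at 112 ± 2.12 and 106 ± 3.55, and AG at 56.5 ± 3.13 and 50.1 ± 2.44. Of the 8 flower organ markers, 5 fell and none rose (5 when adjusted over the list alone), and the list did not pass as deposited (camera adjusted p = 0.059). It passed with no filter (0.046), without Col-0 replicate 2 (0.048) and without cdc5 replicate 1 (0.039), with a range over alternatives of 0.039 to 0.29, and after loess scaling or length and GC adjustment 3 members were lower. AP3 fell with limma adjusted p = 1.1e-05. PI, SHP2 and AG, with limma adjusted p = 0.024, 0.02 and 0.021, lost their calls without some libraries. For PI these were Col-0 replicates 1 and 3 and cdc5 replicates 1 and 3 (0.065 to 0.083). For SHP2 they were Col-0 replicate 3 and cdc5 replicates 2 and 3 (0.069 to 0.07), and for AG Col-0 replicate 1 and cdc5 replicates 2 and 3 (0.057 to 0.075). Over all alternatives the adjusted p ranged from 0.0036 to 0.11 for PI, 0.0048 to 0.07 for SHP2 and 0.0098 to 0.095 for AG. The call of PI also ended with a replicate block, and that of AG under an alternative other than a left-out library.

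Photosynthesis genes gave 9 higher and 1 lower of 23 (10 when adjusted over the list alone), with LHCB2.2 rising from 789 ± 29.8 to 992 ± 4.79 FPKM, LHCB3 from 1270.2 to 1542 and LHCA4 from 1659 to 1846. LHCB1.4 rose from 10.6 to 19.5 FPKM, but the LHCB1 and RBCS genes are near copies whose separate levels are uncertain. The list did not pass as deposited (camera adjusted p = 0.35) and passed after loess scaling, with 15 higher and none lower (3.5e-04), and after length and GC adjustment (0.0082), with a range over alternatives of 3.5e-04 to 0.81. Its median of 0.10 became 0.24 and 0.20 under these, and 0.02 without Col-0 replicate 1. Anthocyanin and flavonoid genes gave 5 higher and 3 lower of 11 (9 when adjusted over the list alone; camera adjusted p = 0.29, or 0.046 with no filter, range over alternatives 0.046 to 0.61). Their median of 0.14 became 0.02 with a filter at 5 FPKM, 0.26 after length and GC adjustment and 0.09 without cdc5 replicate 2. The late genes DFR and LDOX rose from 0.35 to 2.55 and from 1.34 to 4.23 FPKM and CHI from 99.8 to 121 FPKM, and FLS1 fell from 362 to 271 FPKM. Of 10 leaf senescence genes, 4 rose and none fell (4 when adjusted over the list alone; camera adjusted p = 0.19): NYC1, SEN1, SAG13 and NAP, the last of which lost its call after loess scaling (limma adjusted p = 0.061, range over alternatives 0.0041 to 0.061). After length and GC adjustment 1 senescence gene was lower.

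Markers of other tissues were scarce where they were listed. Of the 8 root markers, 5 were listed in the deposited data and 1 was tested. This was COBL9, at 2.95 FPKM in Col-0 and 2.58 in cdc5 (limma adjusted p = 0.22), and CASP2 stood at 0.601 and 0.545 FPKM. Of the 6 seed markers, 4 were listed and none reached the filter, with CRA1 at 0.273 and 0.146 FPKM and SESA1 at 0.02 and 0.099.

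Camera called 8 of the 19 lists, and with an estimated correlation it called 0, of which 3 had an unadjusted p under the threshold. Fry, which does not compare a list with other genes, called 17. Counts of list members called higher or lower stand against 6594 and 4433 of all 19778 genes tested, and only camera compared lists with other genes.

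**Figure D3:**
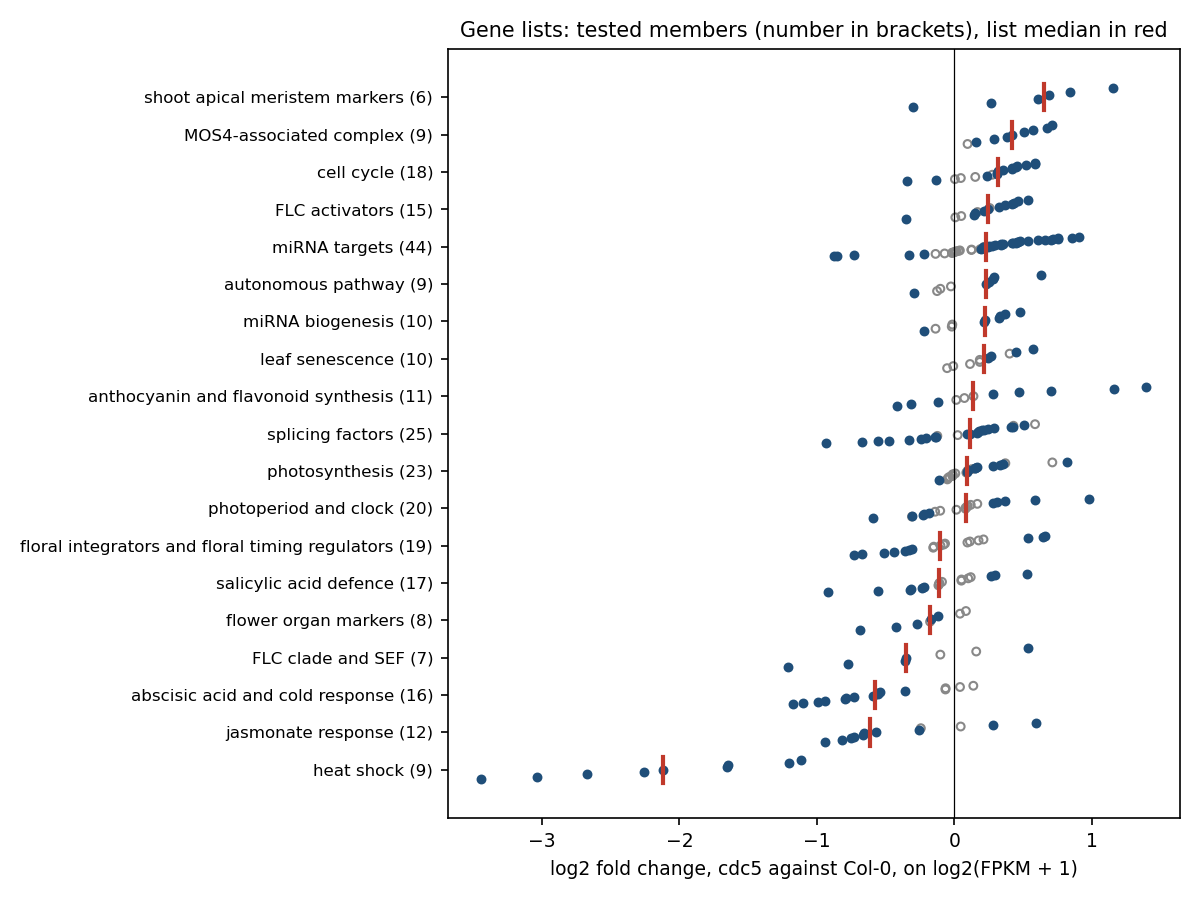
Log2 fold change of cdc5 against Col-0 on log2(FPKM + 1) (horizontal axis) of each tested member of 19 gene lists (vertical axis, number of genes in brackets); filled points passed the limma test, open points did not, and red marks are list medians. Heat shock genes reach the lowest values with a median of -2.12, and meristem markers the highest list median, 0.65; after cyclic loess or length and GC adjustment the autonomous pathway, clock and splicing lists give other balances of higher and lower members.

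At the level of single transcripts, limma called 4898 higher and 3620 lower of 27441 tested, and 956 of the higher and 625 of the lower changed at least 2-fold. After cyclic loess scaling 4231 were higher and 3891 lower, and the balance of 2-fold changes turned to 730 higher and 778 lower. With a filter at 5 FPKM it was 299 higher and 365 lower. Of the 8518 called, 8091 had a q-value under 0.05 and the same direction in the authors' deposited table. In the authors' deposited table, a q-value under 0.05 alone took in 7098 higher and 7218 lower transcripts. The authors' deposited table marked 5566 transcripts as significant, 3366 higher and 2200 lower in cdc5, of which 2499 lay under the filter used here.

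Isoform usage was called as changed in 1187 of 5456 genes tested (limma diffSplice), 658 of them with a share change of at least 20 points. Of the 1187, 709 were also called at the gene level, a case that the simulation did not cover. On the log2(FPKM + 1) scale an equal fold change is smaller for low transcripts. A change of gene level alone can therefore be called as changed usage. The actin-binding villin gene VLN2 (AT2G41740) switched almost fully, from 88.7 ± 1.2% of AT2G41740.2 in Col-0 to 99.5 ± 0.6% of AT2G41740.1 in cdc5. The transcript that was lost holds 230 untranslated bases at chromosome 2, 17417216 to 17417445, which are intronic in the other. EICBP.B (AT5G09410), a calmodulin-binding factor, went from 8.5 ± 3.2% to 95.2 ± 4.0% of AT5G09410.2, which has an added coding exon of 54 bases at chromosome 5, 2923519 to 2923572. AT5G18420 went from 88.9 ± 1.7% to 3.1 ± 3.9% of AT5G18420.2, which differs from the gaining AT5G18420.3 by 9 coding bases at chromosome 5, 6108804 to 6108812, and by its ends.

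The chloride cotransporter gene CCC1 (AT1G30450) went from 6.4 ± 1.4% to 49.1 ± 1.7% of AT1G30450.3, which keeps an untranslated intron of 133 bases at chromosome 1, 10769115 to 10769247. In LOL1 (AT1G32540), AT1G32540.2 fell from 48.8 ± 7.7% to 5.8 ± 0.5%, and AT1G32540.6, which runs 286 bases into an intron at chromosome 1, 11768755 to 11769040, rose from 0.9 ± 1.1% to 20.4 ± 4.1%. The photosystem I gene PSAL (AT4G12800) went from 0.1% to 48.2 ± 0.3% of AT4G12800.2, which differs from AT4G12800.1 only at its ends. Each of these 6 genes had a diffSplice adjusted p of 4.0e-08 or less. Of 16 tested splicing factor genes, 6 were called for isoform usage, against 1187 of all 5456 genes tested, and the difference was not tested. Transcripts of a gene overlap, so shares depend on how shared reads were split between them in the authors' processing. Usage was compared among listed transcripts only, so RNA spliced in other ways was not seen.

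**Figure D4:**
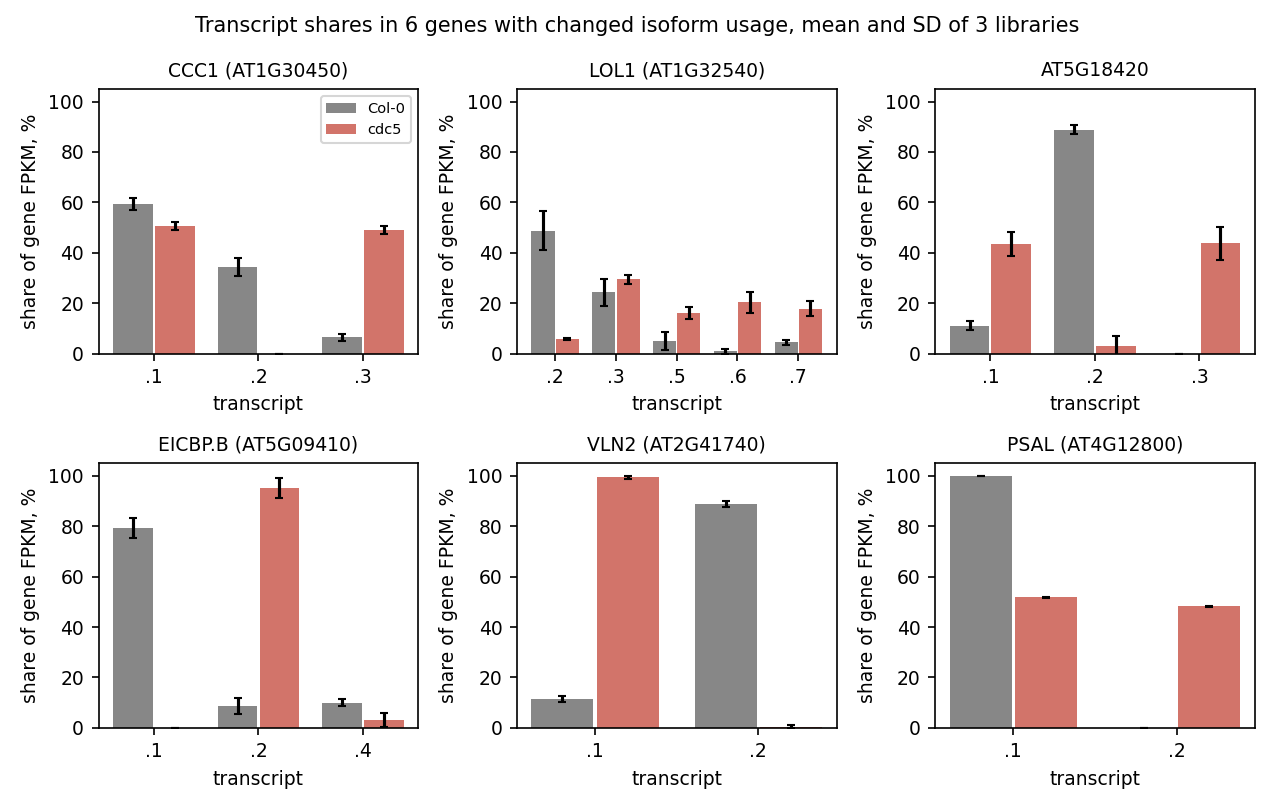
Share of the gene's summed FPKM in percent (vertical axes) of each tested transcript (horizontal axes) of CCC1, LOL1, AT5G18420, EICBP.B, VLN2 and PSAL; bars are means of 3 Col-0 (grey) or cdc5 (red) libraries and error bars SDs. The leading transcript of VLN2 drops from 88.7% to 0.5%, and that of EICBP.B from 79.2% to 0%.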

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

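The length and GC adjustment and the run without overlapping genes were chosen after the results were seen; the other alternatives were planned. Of the 11027 genes called, 9170 kept their call and direction after loess scaling and 8660 after length and GC adjustment, where 10 were called the opposite way. Without each library in turn the number called ranged from 9780 to 10273 genes, 6082 to 6831 transcripts, 893 to 970 genes for isoform usage and 6 to 9 lists, all with fewer samples. Genes changed at least 2-fold numbered 1003 with a pseudocount of 0.1, which shrinks low genes less, and 298 with a filter at 5 FPKM and 344 without overlapping genes, where fewer genes were tested. Isoform usage was called in 1836 genes with no filter and 417 with a filter at 5 FPKM, which change how many transcripts are tested. The authors' q-values called 14316 transcripts, and the cause was not tested. Camera with an estimated correlation called 0 lists and fry 17, as its question differs. MAF5 ranged from -0.22 to -0.03 without single libraries and passed without cdc5 replicate 2 (-0.22, limma adjusted p = 0.033, range over alternatives 0.033 to 0.86), from fewer samples. CDC5, FLC, FLM, MAF2, MAF4 and SEF kept their calls at the gene level under every alternative in which they were tested.

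Of 1240 values of the other named genes under alternatives, 1219 stayed on the same side of the threshold with the same direction and 21 lost the call. For lists these numbers were 222 of 247, with 16 lost and 9 gained. For transcripts of CDC5, the FLC clade and SEF they were 169 of 184 with 15 lost, and for named isoform genes 109 of 116 with 6 lost and 1 gained. Replicate numbers did not pair the samples. Residuals of same-numbered libraries correlated at 0.043, 0.059 and 0.004, and Col-0 replicate 3 correlated at 0.032 with cdc5 replicate 1, so not every library correlated best with its own number. With a replicate block, 10634 genes, 5450 transcripts, 856 genes for isoform usage and 6 lists were called. The block ended the calls of MAF3 isoform usage (adjusted p = 0.065), the FLC and SEF transcripts (limma adjusted p = 0.1 and 0.13), PI (0.11), and the FLC activator and meristem lists (camera adjusted p = 0.052 and 0.059). Count models were not run, since no counts were used here. Depth limits transcripts under the filter, where 3 fragments over 1 kilobase amount to 0.118 to 0.158 FPKM.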

Other observations

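The list of mitochondrial stress genes and the Gene Ontology search were drawn up after the results were seen, as were the length and GC adjustment, the test of exon number at a given length, the test of meristem against flower markers and that of mitochondrial transcripts; the other tests were set out before their values were examined.

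Several genes known from mitochondrial stress were higher in cdc5. Their list was drawn up after the results were seen, includes AT2G41730, already among the 10 highest genes, and was not tested against other genes. Of its 15 tested genes, limma called 10 higher and 1 lower, with a median log2 fold change of 1.57 (10 higher and 3 lower after loess scaling, 10 and 2 after length and GC adjustment). AOX1A, the alternative oxidase, rose from 13.1 ± 0.616 to 86.1 ± 2.16 FPKM (SD, n = 3 each; limma adjusted p = 2.9e-09), the transcription factor NAC013 from 7.34 ± 0.185 to 42.9 ± 1.902, UPOX from 6.43 ± 0.545 to 21.1 ± 1.05 and the NAD(P)H dehydrogenase gene NDB4 from 0.335 ± 0.0900 to 6.26 ± 0.285. The exception was HSP23.5, a mitochondrial chaperone, which fell from 137 to 81.9 FPKM. NDB2, OM66, CYS12 and AAC3 did not pass, with log2 fold changes of 0.09, -0.12, -0.14 and -0.03. Genes read from the mitochondrial genome gave 0 higher and 11 lower of 13 tested, with a median log2 fold change of -1.16, and those of the plastid genome 4 higher and 0 lower of 36. Mitochondrial transcripts made up 0.0296% to 0.0426% of summed FPKM in Col-0 and 0.0135% to 0.0176% in cdc5, after selection for polyadenylated RNA, in which such transcripts are rare.

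Among 1101 Gene Ontology terms, camera called 149 higher and 110 lower, and 171 of these kept their call and direction after length and GC adjustment. With an estimated correlation it called 0, with 169 at an unadjusted p under the threshold. Among the higher terms, RNA helicase activity had the smallest adjusted p, with 70 of 86 genes higher and 0 lower (camera adjusted p = 5.0e-11, and adjusted p = 0.28 with an estimated correlation). For rRNA processing, 110 of 147 genes rose and 8 fell (camera adjusted p = 9.9e-11, and adjusted p = 0.24 with an estimated correlation), for the small-subunit processome 38 of 42 rose and 1 fell, and for DNA replication 68 of 97 rose and 1 fell. DNA replication gave 55 higher and 3 lower after loess scaling and 48 and 8 after length and GC adjustment, where its median log2 fold change of 0.29 became 0.18. RNA helicase activity gave 63 and 0, and 56 and 3. Lower terms included the cellular response to hypoxia, with 111 of 195 genes lower and 20 higher (camera adjusted p = 3.1e-11, and adjusted p = 0.24 with an estimated correlation). Pollen and cell wall terms were also lower. Of 53 genes of the pollen tube term 32 were called lower and 6 higher, and of 54 of pectinesterase activity 36 and 4. Each had a camera adjusted p of 0.24 with an estimated correlation. Of 8 flower organ markers 5 were lower and 0 higher (3 and 0 after loess scaling or length and GC adjustment). In a second list of flower organ genes, ATA7, AMS, A9 and SUP were lower, with log2 fold changes of -0.53, -0.45, -0.25 and -0.48 (limma adjusted p = 1.7e-05, 1.5e-04, 0.0023 and 0.0074), and the anther gene MS1 was higher at 0.41 (limma adjusted p = 0.023), while 0 genes of that list were called higher after loess scaling or length and GC adjustment. TPD1 and SPL, at 0.23 and 0.14, did not pass.

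All 9 heat shock genes were lower in cdc5. A single library does not account for this, since 9 of 9 stayed called lower without any 1 library, nor does scaling, since 9 stayed after cyclic loess. A second list of heat-induced genes fell in the same way, with 11 of 11 lower and no overlap between the genotypes' libraries (median log2 fold change -1.29), among them HSFA7B and MBF1C. Growth or harvest conditions that differed between the genotypes cannot be told apart from the mutation, since all libraries of a genotype may have shared them. An effect of the mutation itself therefore stays open and was not tested.

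Longer genes were higher in cdc5, with a slope of 0.143 log2 units per doubling of length over protein-coding genes. GC content was taken over the gene's genomic span, introns included, so that of the spliced transcript was not tested. GC content of the span does not account for the slope, which was 0.149 with a linear term for it in the model. It was 0.118 (SE 0.0132) among single-exon genes and 0.126 (SE 0.0042) among genes with several exons, so introns are not needed for a rise with length, for which a library difference such as fragmentation or RNA integrity may be a technical cause. Length alone does not account for the whole difference, since exon number kept a slope of 0.044 (SE 0.0032) per doubling with smooth terms for length, level and GC content, and exon number lowered the length slope from 0.143 to 0.105. Each cdc5 library showed it against Col-0 (0.147, 0.141 and 0.141), while libraries set against others of their genotype gave -0.032 to 0.034, so preparation by genotype and an effect of the mutation on long or many-exon transcripts both stay open.

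Flower genes were abundant in libraries labelled rosette leaves. In the second list, of 12 flower organ genes, 10 reached 1 FPKM in both genotypes, among them the anther genes ATA7 at 227 FPKM in Col-0 and 158 in cdc5 and A9 at 157 and 132, which is consistent with flower or inflorescence tissue in the sampled material. Of the 10 tested, 1 was higher and 4 were lower, with a median log2 fold change of -0.09 (0 and 5 with -0.14 after loess scaling, 0 and 3 with -0.07 after length and GC adjustment). A larger share of such tissue in cdc5, with the same make-up as in Col-0, does not account for the higher meristem markers. Such a share would raise both groups, but flower organ markers had a median log2 fold change of -0.17 (-0.11 after loess scaling) and meristem markers one of 0.65. The exact permutation p was 0.004 over genes (two-sided), which are not independent replicates. That test was set out after the results were seen, so its p adds no independent support. A smaller share of inflorescence tissue in cdc5 stays open, as does a different stage or another mix of it at a larger or smaller share. An effect of the mutation on meristem genes also stays open.

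With 3 libraries against 3 there are 10 splits of the samples, too few for a share under 0.05. The real split alone (1 of 10) gave 11027 genes, and the highest other split gave 3. For transcripts these numbers were 8518 and 22, for isoform usage 1187 and 38 genes, and for gene lists 8 and 6.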
